A study of Homo sapiens with 10 samples.

How the data were processed

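HAP1 is a near-haploid human cell line derived from KBM-7, and RNA from wild type and RBM4 knockout HAP1 cells was sequenced in 10 libraries. Libraries were made with a stranded mRNA kit from 65 ng of total RNA each, per the labels' protocols. The protocol text of the single-end libraries is the same as that of the paired-end libraries, so how the single-end libraries were made is not given in the sources used here. ERCC spike-in RNA was added to the RNA, per the labels' protocols, and spike-in values were not used here.

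The deposited tables, 1 for the 8 paired-end libraries and 1 for the 2 single-end libraries, hold whole-number counts of reads per gene and per repeat subfamily, with no normalization, as the values themselves show. Each has 58051 gene rows with Ensembl identifiers and 1187 repeat rows. The column names of the tables give the sample names, and the names of the deposited tables give TEToolkit as the counting tool. Reads were aligned with STAR 2.5.2a to hg38 (GRCh38), per the submitters' processing notes. The version of the counting tool, its strand setting, its handling of reads with several alignments and the annotation release are not given in the sources used here. Gene symbols came from a gene name table (56948 of the identifiers matched) and from GENCODE 29 (57447 had coordinates), and coordinates are those of GENCODE 29 on GRCh38.

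Samples were grouped as wild type (n = 3), RBM4 knockout clone 1 (n = 3), RBM4 knockout clone 2 (n = 2), single-end wild type (n = 1) and single-end RBM4 knockout clone (n = 1). Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. No library was a copy of another: within groups, the chi-square per degree of freedom of replicate pairs lay between 5.02 and 25.2.

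The main tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Counts of genes and repeats were filtered with edgeR's filterByExpr, which left 20747 features (19683 genes and 1064 repeat subfamilies), and scaled with TMM factors. Each feature was tested with edgeR's quasi-likelihood F test (robust fit, 1 mean per group over the 8 paired-end libraries). The contrasts were clone 1 against wild type, clone 2 against wild type, the mean of the clones against wild type, and clone 2 against clone 1. P-values were adjusted with the Benjamini-Hochberg method over all features, and a feature was called at an adjusted p below 0.05. Unless another contrast is named, a log2 fold change or adjusted p belongs to the mean of the clones against wild type. Levels are CPM, counts scaled by the TMM-adjusted library sizes. An SE is the absolute log2 fold change divided by the square root of the F statistic. It is approximate and can be smaller than the counting error where a group has few counts. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

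In all, 46 gene and repeat lists, written from textbook knowledge, were tested with limma's camera on voom values with a preset correlation between genes of 0.01, and adjusted over the 46 lists. Each was also tested with an estimated correlation and with fry. The HERV-W and LTR17 list had too few measured members to test. Counts of called members are given over all features and adjusted over the list alone.

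Genes were named by a fixed rule. It took RBM4, RBM4B, RBM14 and RBM14-RBM4. It took the 12 genes that rose and the 12 that fell most among those called the same way in both clones, with a mean log2 CPM of at least 1 and every knockout library beyond every wild type library. It took up to 2 called members per list and direction, or the member with the smallest p where none was called. It took HERVH-int, LTR7, HERVK-int, LTR5_Hs, L1HS and up to 5 repeats per direction under the same criteria, and the 6 genes per direction that differed most between the clones. Names outside the rule, used to complete small counts or as further examples, were chosen after their values were seen. Of the list members taken by the rule, 2 genes are not reported here.

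The single-end pair has no replicates and was used as values only. Its log2 fold changes used a prior count of 2 for features with at least 20 counts in the pair. Ratios with 1 to 3 counts in a group, and that of ALDH1A2 in clone 1, have exact 95% intervals. Shares have exact Clopper-Pearson intervals. All such intervals cover counting error only.

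The same code was tested on simulated counts with the real means and library sizes and 200 changed features. For the mean of the clones, edgeR recovered 74% of features changed 1.3-fold, 90% of those changed 1.5-fold and 100% of those changed 2-fold, and called 12 of 20547 unchanged features. With a simulated GC trend it called 805 unchanged features, and 27 after GC correction. The simulated shifted list was called, as were 0 of 20 unshifted lists.

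Total counts ran from 33192095 to 55617525 per paired-end library. Alternatives fixed in advance were DESeq2 size factors, TMM factors from genes only, no filter on low counts, DESeq2's Wald test, and the replicate number as a block. Further ones were all knockout libraries as 1 group, a 1.5-fold minimum on the estimated change, list tests with other settings, and each library left out in turn. Alternatives chosen after seeing the data were a GC correction, a term for the block of sample numbers, the first block of sample numbers only, and the correlation of the clones with each library left out or with the wild type libraries divided between the clones. The GC correction fitted a spline with 4 degrees of freedom per library to the GC content of each gene's longest GENCODE 29 transcript, known for 19549 genes, and left repeats as they were. Sample numbers stand in the column names of the table: numbers 1 to 5 are the 3 wild type libraries and the first replicate of each clone, and numbers 11 to 13 are the other 3 knockout libraries. What the numbers mean is not given in the sources used here. With 2 to 3 libraries per group, comparisons rest on the spread that edgeR pools across genes and groups.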

Results

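RNA from wild type HAP1 cells and from 2 RBM4 knockout clones was sequenced, and reads were counted per gene and per repeat subfamily. The paired-end libraries comprised 3 of wild type, 3 of clone 1 and 2 of clone 2, and 1 wild type and 1 knockout library were sequenced single-end. Total counts were 42245194, 35325400 and 42128476 in the wild type replicates, 33192095, 55617525 and 39789255 in clone 1, and 40060383 and 46690703 in clone 2. The single-end libraries held 44140706 counts (wild type) and 41265510 counts (knockout). Repeats took 3.56% to 5.37% of the counts of the paired-end libraries, and 8.51% and 10.4% of those of the single-end wild type and knockout libraries. In a principal component analysis of the paired-end libraries, the first component (38.4% of the variance) separated wild type from knockout and the second (21%) separated the clones. The series title gives the purpose as finding genes that differ between wild type and RBM4 knockout HAP1 cells.

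RBM4 encodes an RNA-binding protein that regulates splicing and translation, and it was the gene targeted. RBM4 RNA (ENSG00000173933, chromosome 11, 66638617 to 66668374) stood at 79.9, 79.8 and 78.7 CPM in the wild type replicates, 22.3, 22.9 and 24.5 CPM in clone 1, and 25.3 and 25.8 CPM in clone 2. It fell 3.26-fold in the mean of the clones (log2 fold change -1.70, SE 0.048, adjusted p = 1.11e-10). The log2 fold change was -1.77 in clone 1 and -1.64 in clone 2, and the clones did not pass the test of their difference (adjusted p = 0.523). The read-through gene RBM14-RBM4 (ENSG00000248643, 66616626 to 66646469) also fell (log2 fold change -1.35, SE 0.046, adjusted p = 3.84e-10), from 82.8 CPM to 31.4 and 33.6 CPM. RBM4B (ENSG00000173914, 66664998 to 66677921), the closest paralog of RBM4, rose from 30.4 ± 0.278 CPM (SD, n = 3) to 48.6 ± 3.12 CPM in clone 1 (n = 3) and 47.0 ± 1.98 CPM in clone 2 (n = 2). Its log2 fold change was 0.65 (SE 0.055, adjusted p = 3.21e-06). RBM14 (ENSG00000239306, 66616582 to 66627347) was not called (0.01, adjusted p = 0.900), with a sign that turned under TMM factors from genes only, under GC correction (-0.13), and without wild type replicate 3, clone 1 replicate 3 or clone 2 replicate 1. These genes share exons or overlap on opposite strands and the strand setting of the counting is not given, so their separate values are uncertain. Of the 15 measured genes of the RBM4 locus list, 7 rose and 2 fell, the same numbers adjusted over the list alone. The list was not called (adjusted p = 0.0590, or 0.539 with an estimated correlation). Among these genes, the lysosomal protease gene CTSF rose by 0.73 (adjusted p = 2.12e-06).

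**Figure D1:**
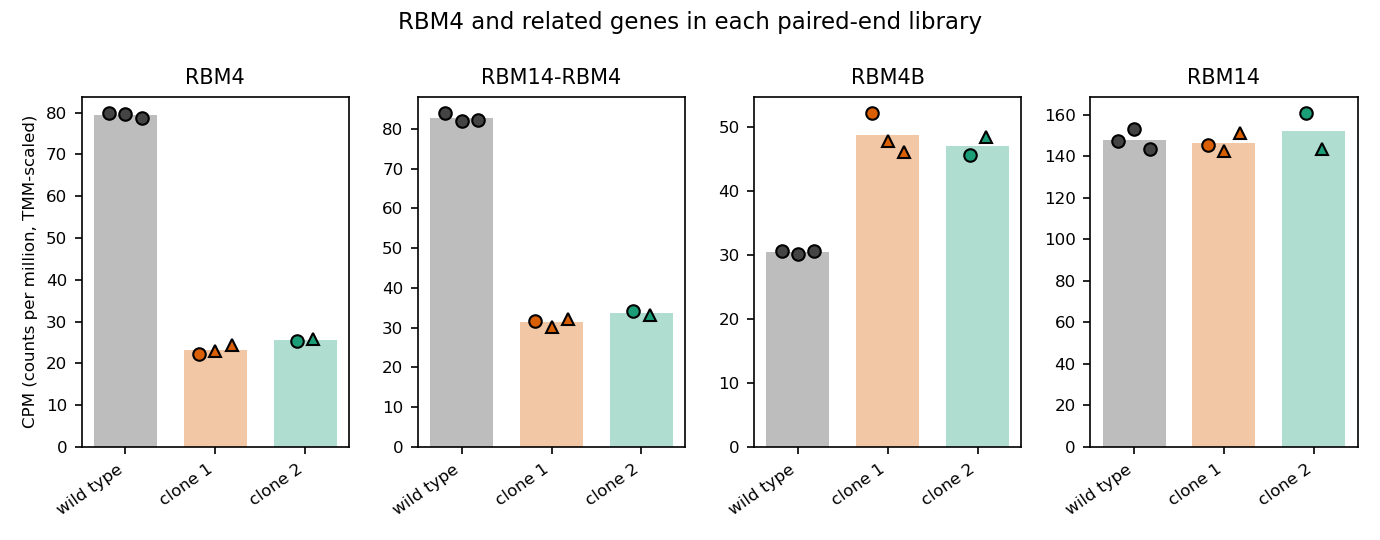
CPM of RBM4, RBM14-RBM4, RBM4B and RBM14 in each paired-end library, with bars at the group means, circles for sample numbers 1 to 5 and triangles for 11 to 13. RBM4 lies between 78.7 and 79.9 CPM in wild type and between 22.3 and 25.8 CPM in the clones.

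ALDH1A2 (ENSG00000128918, chromosome 15, 57953424 to 58497866), which makes retinoic acid, fell from 50.8 ± 2.27 CPM (SD, n = 3) to 0.0966 CPM in clone 1 and 0.582 CPM in clone 2 (log2 fold change -7.69, SE 0.12, adjusted p = 1.71e-13). It had 13 counts in clone 1, a ratio of wild type to clone 1 of 506 (95% interval 295 to 950), so its SE is likely too small. SLC16A7, a monocarboxylate transporter, fell from 10.3 to 0.308 and 0.299 CPM (-5.12, SE 0.16), and ABCB1, the drug efflux pump P-glycoprotein, from 23.1 to 8.26 and 0.991 CPM (-3.01, SE 0.085). Others that fell most were ZNF385D (-5.12), ITPRIPL1 (-4.69), LGALS8 (-3.77), which encodes galectin-8, and the class V myosin MYO5C (-3.47). They were followed by CSRP1 (-3.36), SLITRK3 (-3.02), CSMD1 (-2.61), the protocadherin PCDH17 (-2.56) and PKN2-AS1 (-2.55), an antisense RNA that is uncertain without the strand setting. VCAM1 (ENSG00000162692, chromosome 1, 100719742 to 100739045), a cell adhesion receptor, rose from 0.157 ± 0.104 CPM (SD, n = 3) to 2.35 ± 0.242 CPM in clone 1 and 6.28 ± 1.67 CPM in clone 2 (log2 fold change 4.63, SE 0.30, adjusted p = 3.86e-07). The secreted matrix glycoprotein THBS1 rose by 3.86 (SE 0.29) and DIO2, which activates thyroid hormone, by 3.64 (SE 0.21). The growth factor receptor PDGFRA rose by 3.07 (SE 0.11), a mean of 0.77 in clone 1 and 5.38 in clone 2. FOXF1, a forkhead transcription factor of mesenchyme, rose from 2.77 to 22.5 and 12.7 CPM (2.60, SE 0.11). The other genes that rose most were the salt transporter SLC12A3 (2.98), DTNA (2.5), HR (2.29), PRDM16 (2.29) and the bicarbonate transporter SLC4A5 (2.25). With them were SGCD (2.61, with 1.55 in clone 1 and 3.67 in clone 2) and the growth factor BMP7 (2.41, with 0.94 and 3.87). Several rises and falls named here differed in size between the clones, as given below, and an SE does not cover that difference. An SE can also be too small for genes with few counts in a group.

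In the mean of the clones, 3725 of 20747 features passed edgeR's test, 2028 genes and 19 repeat subfamilies up and 1670 genes and 8 repeats down. Clone 1 had 3321 (1944 up, 1377 down) and clone 2 had 2236 (1283 up, 953 down). Both clones changed the same way in 1549 genes (908 up, 641 down), 370 of them by at least 2-fold (255 up, 115 down), and in opposite ways in 37 features. The excess of rises did not hold with the sample-number term (1018 genes up and 1202 down in both clones) or in the first block of sample numbers alone (820 up and 1133 down). Fold changes of the clones correlated across features (Pearson 0.649, Spearman 0.673), where unchanged groups simulated against the same wild type libraries gave a mean Pearson of 0.455, and features are not independent replicates. Their covariance was 0.176 against a simulated 0.0247, a difference of 0.151. Independent lists of these sizes would share 120 features up and 63.3 down by chance, and the clones shared 916 and 642. Simulated unchanged groups shared at most 2, but almost nothing could be called in them. Their overlap is therefore no baseline for clones with many calls each. The wild type libraries were also divided 1 and 2 between the clones, in 6 ways, so that none was shared. The covariance was then 0.150 to 0.168, the Pearson correlation 0.434 to 0.509, and 324 to 393 features were called the same way. What the 3 wild type libraries have in common still enters both comparisons, so part of the excess may come from the shared controls. Without wild type replicate 1 the counts were 1605 in clone 1, 1268 in clone 2, 1847 in the mean and 801 genes in both. Without wild type replicate 2 they were 1928 in clone 1, 2217 in the mean and 999 in both. The mean gave 2443 without wild type replicate 3, clone 2 gave 1033 and 1449 without its replicates 1 and 2, and 766 genes changed in both clones without clone 2 replicate 1. A fit with all knockout libraries as 1 group ended the calls of PDGFRA (adjusted p = 0.184), SGCD (0.0753), BMP7 (0.147), ABCB1 (0.111) and PCDH17 (0.0509), whose sizes differed between the clones.

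**Figure D2:**
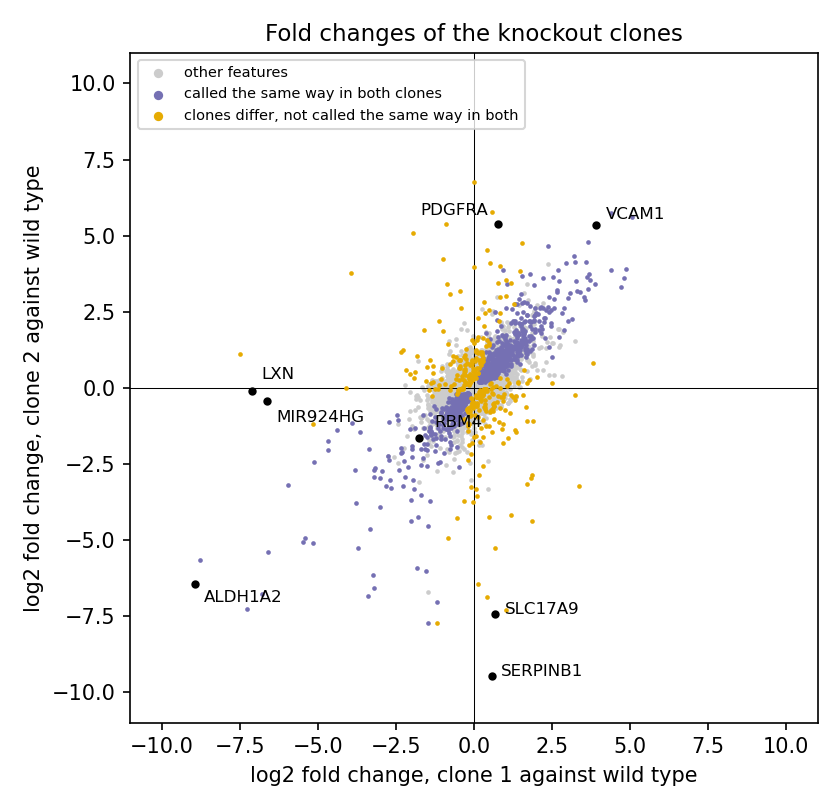
Log2 fold change against wild type of each tested feature in clone 1 (horizontal axis) and clone 2 (vertical axis); purple points were called the same way in both clones and orange points differ between the clones without such a call. VCAM1, PDGFRA, RBM4 and ALDH1A2 are labelled among the former and LXN, MIR924HG, SLC17A9 and SERPINB1 among the latter.

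The fold changes followed the GC content of the genes. Of 2149 genes below 40% GC, 53 rose and 650 fell (median log2 fold change -0.15), and of 1910 genes at 60% GC or more, 405 rose and 35 fell (median 0.11). Within each library, the Spearman correlation across genes of level (relative to the gene's mean) with GC was -0.54, -0.46 and -0.36 in wild type, 0.38, -0.08 and 0.54 in clone 1, and 0.52 and -0.10 in clone 2. The difference of group means was 0.708 (exact permutation test over 56 splits, two-sided p = 0.0357). This test was not among those fixed in advance, and it treats the 5 knockout libraries, from 2 clones, as exchangeable. Within sample numbers 1 to 5, the GC correlations of the clones were 0.38 and 0.52 against the 3 negative wild type values, and numbers 11 to 13 hold knockout libraries only. Levels also followed gene length (Spearman 0.19, 0.19 and 0.08 in wild type, -0.39, 0.13 and -0.11 in clone 1, and -0.25 and 0.19 in clone 2). No fit corrected for length, and its part in the fold changes was not tested. Across genes, fold change correlated with GC at 0.527 in the mean of the clones and at -0.0206 in the single-end pair. With a GC correction 3148 features were called in the mean, of which 2254 were among the 3725 called without it. Of the 370 genes changed at least 2-fold in both clones, 344 were still called in both. Of the 1179 changed less, 661 were.

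**Figure D3:**
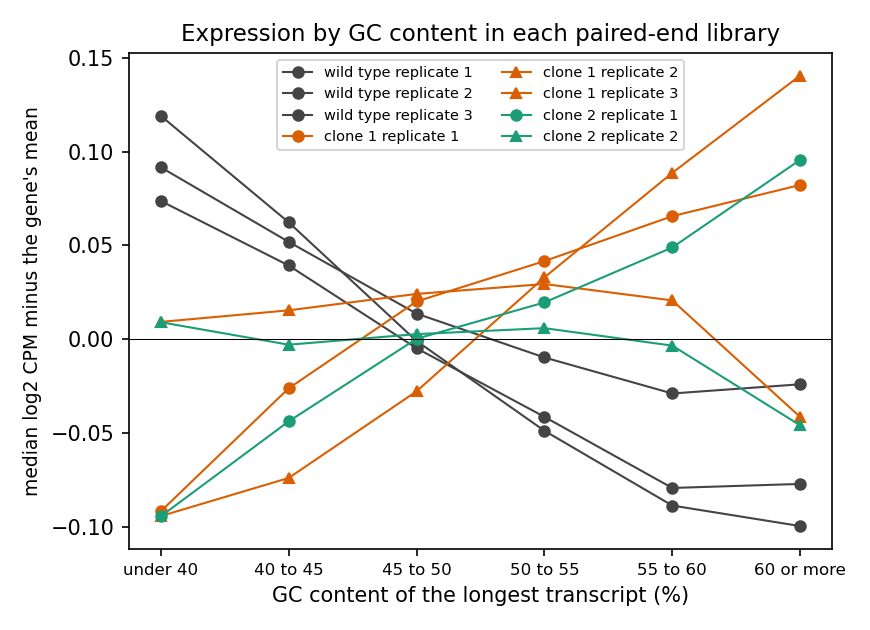
Median log2 CPM of genes relative to each gene's mean over the 8 paired-end libraries (vertical axis), by GC content of the longest transcript (horizontal axis), with 1 line per library. The wild type lines fall with GC, from 0.12, 0.07 and 0.09 below 40% GC to -0.10, -0.08 and -0.02 at 60% or more.

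Some regulators of splicing, the process RBM4 itself takes part in, were lower in the clones before GC correction. Of 59 measured, 0 rose and 19 fell in edgeR's test (2 rose and 26 fell adjusted over the list alone, 2 and 32 at an unadjusted p below 0.05, 0 and 21 with DESeq2). MBNL3, a muscleblind-family regulator, fell by 0.52 (SE 0.057, adjusted p = 3.07e-05), and NOVA1, a neuronal one, fell by 0.46 (SE 0.070, adjusted p = 0.000542). The list median was -0.12 (camera adjusted p = 1.31e-06, or 0.244 with an estimated correlation). Its members have a median GC of 41%. With GC correction the list median was -0.02, 3 rose and 10 fell, and the list was not called (camera adjusted p = 0.122). The uncorrected call and the list calls below used the preset correlation, with which 60 of 100 splits of the libraries gave at least 14 called lists. A list call with the preset correlation therefore cannot exclude chance by itself, however small its adjusted p.

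Several genes of cell division fell slightly. Of 30 mitosis genes, 0 rose and 9 fell in edgeR's test, the same adjusted over the list alone (0 and 11 at an unadjusted p below 0.05, 0 and 8 with DESeq2). They were led by ECT2 (-0.30, SE 0.067), a regulator of cytokinesis, and DLGAP5 (-0.26, SE 0.049), a spindle protein (list median -0.10, adjusted p = 0.000165, or 0.539 with an estimated correlation and 0.0677 with fry). Of 35 DNA replication genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone, 0 and 13 at an unadjusted p below 0.05, 0 and 9 with DESeq2). They were led by the cyclin gene CCNE2 (-0.28, SE 0.056) and GINS1 (-0.26, SE 0.051) of the replicative helicase (median -0.04, adjusted p = 0.00408, or 0.532 with an estimated correlation). The median GC was 43.2% and 48.7%, and GC correction kept both list calls (adjusted p = 0.00177 and 3.38e-05) but ended those of DLGAP5 (0.0578) and CCNE2 (0.0971). Replication-dependent histone genes went the other way. Of 13, 8 rose and 0 fell (9 and 0 adjusted over the list alone and at an unadjusted p below 0.05, 6 and 0 with DESeq2), with H2AC8 at 1.16 (SE 0.36) and H2BC11 at 1.11 (SE 0.24). The list median was 0.72 (adjusted p = 0.000165, or 0.271 with an estimated correlation). These RNAs mostly lack poly(A) tails, share sequence with one another and stood at low levels, with H2BC11 at 0.477 CPM in wild type. The call of H2AC8 ended under 11 of 17 alternatives (adjusted p up to 0.158), among them the GC correction, the sample-number term and leaving out any wild type replicate, clone 1 replicate 3 or either clone 2 replicate.

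Many genes that respond quickly to growth signals rose. Of 27 immediate early genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone, 17 and 0 at an unadjusted p below 0.05, 11 and 0 with DESeq2). They included the transcription factor genes JUN (1.60, SE 0.13, adjusted p = 1.79e-06) and FOSL2 (1.37) and the phosphatase genes DUSP6 (1.11) and DUSP4 (0.89). SPRY4, an inhibitor of receptor signalling, had 2 counts in wild type, and its ratio was 11 in clone 1 (95% interval 2.73 to 96.1) and 20.3 in clone 2 (5.15 to 175). The list median was 0.35 (adjusted p = 1.93e-05, or 0.244 with an estimated correlation), its median GC was 53.9%, and with GC correction 9 rose and 2 fell (adjusted p = 0.000229). Of 38 genes of the unfolded protein and integrated stress response, 12 rose and 0 fell (13 and 0 adjusted over the list alone, 16 and 0 at an unadjusted p below 0.05, 11 and 0 with DESeq2). NUPR1 rose by 2.01 (SE 0.58) and PPP1R15A, which restores translation after stress, by 0.57 (SE 0.10). That list's median was 0.09 (adjusted p = 0.00445, or 0.671 with an estimated correlation and 0.0708 with fry) and its median GC 50.9%; with GC correction 6 rose and 3 fell (adjusted p = 0.0369). With the preset correlation that list was called in clone 2 (10 rose and 0 fell, camera adjusted p = 0.000748). In clone 1 it was not (5 rose and 0 fell, 0.0610), though it was with the sample-number term (0.00112). NUPR1, at 0.0844 CPM in wild type, lost its call under 8 of 17 alternatives (adjusted p up to 0.471), including the sample-number term and leaving out any wild type replicate, clone 1 replicate 2 or 3, or clone 2 replicate 1.

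Interferon-stimulated genes moved both ways, more of them up. Of 43 measured, 12 rose and 3 fell (17 and 4 adjusted over the list alone, 13 and 6 with the sample-number term). The RNA sensor IFIH1 (1.12, SE 0.15, adjusted p = 0.000253) and OAS1 (1.59, SE 0.40) rose, and IFIT1 (-0.56, SE 0.12), TRIM22 (-0.35, SE 0.098) and IFIT5 (-0.19) fell. The median was 0.17 (adjusted p = 0.00951, or 0.334 with an estimated correlation). OAS1 stood at 0.144 CPM in wild type and lost its call in the first block alone and without wild type replicate 1 or 2 or clone 2 replicate 2 (adjusted p up to 0.0891). IFIT1 lost its call without wild type replicate 1 (0.0514). TRIM22 lost it with GC correction and without wild type replicate 2 or 3, clone 1 replicate 3 or clone 2 replicate 1 (up to 0.107). Among 19 nucleic acid sensing genes, STING1 (1.64, SE 0.23) and IFIH1 rose, and IFI16 (-2.84, SE 0.50), CGAS (-1.29, SE 0.35; -0.20 in clone 1 and -2.38 in clone 2) and RNASEH2B (-0.20) fell, the same numbers adjusted over the list alone (list adjusted p = 0.995). CGAS lost its call with the sample-number term, in the fit of all knockout libraries as 1 group, and without wild type replicate 1 or 3 or clone 2 replicate 1 (up to 0.453). Of 34 retroelement silencing factors, 3 rose and 7 fell (3 and 8 adjusted over the list alone, 3 and 12 with the sample-number term, list adjusted p = 0.272). The 3 were the antiviral deaminase genes APOBEC3C (2.25, SE 0.10, adjusted p = 5.62e-09), APOBEC3B (0.93, SE 0.17; 1.70 in clone 1 and 0.15 in clone 2) and APOBEC3F (0.62), paralogs that can share reads. The 7 that fell included HELLS (-0.38), a chromatin remodeller, and ATF7IP2 (-0.28). HELLS lost its call with GC correction, with the replicate block and without wild type replicate 1 or 2, clone 1 replicate 2 or clone 2 replicate 1 (up to 0.178). ATF7IP2 lost it with GC correction and without wild type replicate 1 (up to 0.0887). APOBEC3B lost it with the knockout libraries as 1 group (0.117).

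Of 13 epithelial markers, 6 rose and 0 fell (8 and 0 adjusted over the list alone, 9 and 0 at an unadjusted p below 0.05, 5 and 0 with DESeq2). These included the keratin genes KRT17 (1.98, SE 0.49), KRT8 (1.09) and KRT18 (0.50) and the junction gene CLDN7 (1.36, SE 0.41). The median was 0.50 (adjusted p = 0.000219, or 0.244 with an estimated correlation), the median GC was 57.5%, and with GC correction 6 rose and 0 fell, CLDN7 not among them (adjusted p = 0.000156). KRT17, at 0.0873 CPM in wild type, lost its call in the first block alone and without wild type replicate 1 or 3 (up to 0.0713). CLDN7 lost it under 9 of 17 alternatives (up to 0.135), including GC correction, the sample-number term and leaving out any wild type replicate, clone 1 replicate 3 or clone 2 replicate 1. Imprinted genes, expressed from 1 parental copy, rose in 6 of 16 cases and fell in 1 (7 and 1 adjusted over the list alone). The growth factor gene IGF2 rose by 2.44 (SE 0.21, adjusted p = 3.55e-06), L3MBTL1 by 1.5 (SE 0.26; 0.82 in clone 1 and 2.19 in clone 2), PHLDA2 by 1.01, DLK1 by 1.00, MEST by 0.98 and PEG10 by 0.64, and ZDBF2 fell (-0.31, SE 0.077). That median was 0.19 (adjusted p = 0.0108, or 0.334 with an estimated correlation), and ZDBF2 lost its call with GC correction and without wild type replicate 1 (up to 0.0758). With the preset correlation the imprinted list was called in clone 2 (6 rose and 0 fell, camera adjusted p = 0.00159). In clone 1 it was not (3 rose and 1 fell, 0.0903). Cholesterol synthesis genes rose slightly, 5 of 24, and 0 fell (6 and 0 adjusted over the list alone, 11 and 1 at an unadjusted p below 0.05, 4 and 0 with DESeq2). They were PMVK (0.37, SE 0.061), HSD17B7 (0.29, SE 0.080), FDPS (0.23), LSS (0.19) and NSDHL (0.17). Its median was 0.08 (adjusted p = 0.0147, or 0.539 with an estimated correlation), and the list was not called with GC correction (0.0567), without wild type replicate 2 (0.0877) or without clone 1 replicate 1 (0.0555). HSD17B7 lost its call without wild type replicate 1 or 2 or clone 2 replicate 1 (up to 0.133).

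Genes of mesenchyme and matrix changed in both directions: 9 of 24 rose and 6 fell, the same adjusted over the list alone. The list was not called (camera adjusted p = 0.0890, and 0.00229 with fry, which tests against no change). Besides THBS1 and PDGFRA, the matrix protein gene SPARC rose by 2.04 and the collagen gene COL5A2 by 1.3. By contrast, THBS2 (-0.80; 0.00635 in clone 1 and -1.60 in clone 2), a relative of THBS1, and the transcription factor gene ZEB2 (-0.38) fell; THBS2 lost its call with the knockout libraries as 1 group (adjusted p = 0.599). Of 19 neuronal genes, 6 rose, including L1CAM (1.07) and SNAP25 (1.36), and 3 fell, SYT1 (-1.42), NLGN1 (-1.11) and CNTN1 (-1.03), the same adjusted over the list alone (list adjusted p = 0.510). SNAP25 lost its call under 7 of 17 alternatives (up to 0.210), among them leaving out wild type replicate 1 or 2, clone 1 replicate 1 or 2, or clone 2 replicate 1. Of 11 pluripotency genes, ESRG (1.82, SE 0.10) and LINC00458 (0.47) rose, both derived from HERV-H and so open to shared reads. In the same list SALL4 (-1.43), LIN28B (-0.40), POU5F1 (-0.31) and TFCP2L1 (-0.19) fell (2 rose and 5 fell adjusted over the list alone; list adjusted p = 0.682). ESRG lost its call with the knockout libraries as 1 group (0.0712), and LINC00458 with the sample-number term, in the first block alone and without any 1 wild type replicate (up to 0.123). SALL4, at 0.326 CPM in wild type, lost it under 7 of 17 alternatives (up to 0.149), including the sample-number term, the knockout libraries as 1 group, and leaving out wild type replicate 1 or 2 or clone 2 replicate 1. Of 10 haematopoietic markers, the integrin gene ITGA2B (0.79) and GATA2 (0.29) rose and the receptor gene KIT (-0.90) fell, the same numbers adjusted over the list alone (list adjusted p = 0.510). GATA2 lost its call with GC correction (0.0502).

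The lists of p53 targets, apoptosis regulators, NF-kB targets and heat shock genes were not called by camera with the preset correlation. Of 26 p53 targets, GDF15 (2.23), TP53I3 (0.36), BTG2 (0.34), SESN2 (0.23) and DDB2 (0.20) rose and FAS (-0.54), ZMAT3 (-0.36) and MDM2 (-0.22) fell (6 and 3 adjusted over the list alone; list adjusted p = 0.995). GDF15, at 0.0540 CPM in wild type, lost its call in the first block alone and without wild type replicate 1 or 3 or clone 2 replicate 1 (up to 0.108), and TP53I3 without wild type replicate 1 (0.0662). FAS lost it without wild type replicate 3 (0.0867) and ZMAT3 without wild type replicate 2 or 3 (up to 0.0700). GC correction also ended the calls of TP53I3 (0.0585) and ZMAT3 (0.0646). Of 28 apoptosis regulators, the BH3-only genes HRK (0.96, with 0.29 in clone 1 and 1.63 in clone 2) and BMF (0.76), with BOK (0.62) and BCL2L1 (0.30), rose and APAF1 (-0.18) fell. The numbers were the same adjusted over the list alone (list adjusted p = 0.231, but 0.0483 with GC correction, and 0.00942 against no change with fry). HRK lost its call with the knockout libraries as 1 group (0.160), and APAF1 with it (0.0562), with GC correction and without any 1 wild type replicate or clone 2 replicate 1 (up to 0.117). Of 15 NF-kB targets, RELB (0.82), TRAF1 (0.53), NFKBIA (0.50) and NFKB2 (0.38) rose and PTGS2 (-0.70) fell (6 and 1 adjusted over the list alone, list adjusted p = 0.0590, and 0.00382 against no change with fry). TRAF1 and PTGS2 each lost the call under 10 of 17 alternatives (up to 0.219), both with GC correction, with the sample-number term and without wild type replicate 1 or 2, clone 1 replicate 3 or clone 2 replicate 1. TRAF1 also lost it without wild type replicate 3 or clone 2 replicate 2, and PTGS2 without clone 1 replicate 2. Of 16 heat shock genes, the small chaperone gene CRYAB (2.74) and DNAJB4 (0.26) rose and HSP90AA1 (-0.31), HSPE1 (-0.23) and HSPA4L (-0.18) fell (2 and 7 adjusted over the list alone; list adjusted p = 0.510). DNAJB4 lost its call with the sample-number term, in the first block alone and without wild type replicate 2 or 3 or clone 2 replicate 2 (up to 0.104). HSPE1 lost it under the same 2 block fits and without wild type replicate 1 or 3 or clone 2 replicate 2 (up to 0.143).

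The lists of glycolysis, hypoxia, respiratory chain, mitochondrially encoded, ribosomal protein, clock and zinc finger genes were not called in the uncorrected test, though 4 of them were with a correction. Of 24 glycolysis genes, ENO2 (0.58), PFKL (0.26) and HK1 (0.21) rose and the transporter genes SLC2A3 (-0.40) and SLC16A1 (-0.27), PDK1 (-0.29) and HK2 (-0.19) fell, the same numbers adjusted over the list alone (list adjusted p = 0.941). With GC correction 2 rose and 5 fell and the list was called lower (0.0473). PFKL lost its call with GC correction (0.0753). Of 24 hypoxia genes, ANGPTL4 (1.44) and NDRG1 (0.92) rose and SLC2A3, PDK1, ERO1A (-0.23) and P4HA1 (-0.21) fell, the same adjusted over the list alone (list adjusted p = 0.243). ANGPTL4, at 0.134 CPM in wild type, lost its call under 11 of 17 alternatives (up to 0.170), among them GC correction, the sample-number term and leaving out any 1 library except clone 1 replicate 2. SLC2A3 lost its call with the sample-number term, in the first block alone, with the knockout libraries as 1 group, and without wild type replicate 1 or 3 or clone 2 replicate 2 (up to 0.169), and PDK1 without wild type replicate 1 and with GC correction (up to 0.0810). Of 50 nuclear respiratory chain genes, 2 rose, including NDUFB8 (0.26), and 0 fell (1 and 0 adjusted over the list alone, 6 and 0 at an unadjusted p below 0.05; list adjusted p = 0.284). With the sample-number term 8 rose and 0 fell and that list was called higher (7.17e-05 with the preset correlation, the only one used with the term). Without the term its adjusted p was 0.997 with an estimated correlation. None of 13 mitochondrially encoded genes (list adjusted p = 0.934; MT-CO3 at -0.11, adjusted p = 0.376) or 63 cytosolic ribosomal protein genes (list adjusted p = 0.367) was called in the mean of the clones by edgeR or DESeq2, over all features or adjusted over the list alone. In clone 1, 1 ribosomal protein gene rose, and 0 did adjusted over the list alone. Of these lists, 0 and 2 members had an unadjusted p below 0.05. The ribosomal protein list was called in opposite directions by the corrections: higher with the sample-number term (0.0237, 2 rose and 0 fell) and lower with GC correction (0.0352, 0 rose and 4 fell). Of 19 clock genes, the nuclear receptor gene NR1D1 (0.29) and the kinase gene CSNK1D (0.17) rose and RORA (-0.46; -0.23 in clone 1 and -0.68 in clone 2) fell (1 and 1 adjusted over the list alone; list adjusted p = 0.746). NR1D1 lost its call under 15 of 17 alternatives (up to 0.292), among them GC correction and leaving out any 1 library. CSNK1D lost it with GC correction (0.515), with the sample-number term (0.0575) and without wild type replicate 1 or 2 or either clone 2 replicate (up to 0.155), and RORA with the knockout libraries as 1 group (0.116). Of 442 ZNF-named zinc finger genes, 27 rose, including ZNF532 (1.62) and ZNF157 (1.05), and 34 fell, including ZNF804A (-3.19) (23 and 30 adjusted over the list alone; list adjusted p = 0.558); ZNF157 lost its call without wild type replicate 1 (0.0509). With the sample-number term 26 rose and 80 fell and the zinc finger list was called lower (0.0350 with the preset correlation, the only one used with the term). Without the term its adjusted p was 0.997 with an estimated correlation. In the first block of sample numbers alone the list median was -0.05. In the lists of nucleic acid sensing, retroelement silencing, p53, heat shock, glycolysis, hypoxia, mitochondrially encoded, haematopoietic and pluripotency genes and of satellites, the median, the mean and the test differed in sign, and none of these was called in the uncorrected test.

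Endogenous retroviruses of the HERV-H family were higher in both clones. HERVH-int, the internal part of HERV-H, rose from 386 ± 10.2 CPM (SD, n = 3) to 583 ± 49.2 CPM in clone 1 (n = 3) and 575 ± 20.6 CPM in clone 2 (n = 2). Its log2 fold change was 0.58 (SE 0.058, adjusted p = 1.33e-05). Its promoters LTR7 (0.41, SE 0.060), LTR7B (0.31) and LTR7Y (0.98, SE 0.098, adjusted p = 1.44e-05) rose too. In all, 4 of the 6 measured HERV-H and LTR7 subfamilies rose and 0 fell (5 and 0 adjusted over the list alone, and 4 and 0 with DESeq2). The list median was 0.39 (adjusted p = 0.000161, or 0.271 with an estimated correlation). Of the 5 HERV-K HML-2 and LTR5 subfamilies, LTR5_Hs, the youngest promoter type, rose by 0.40 (SE 0.066, adjusted p = 0.00115) and 0 fell (4 and 0 adjusted over the list alone, and 2 and 0 with DESeq2). That list's median was 0.40 (adjusted p = 0.0153, or 0.539 with an estimated correlation, 0.0812 with the sample-number term and 0.0643 with fry). HERVK-int was not called (0.57, SE 0.17, adjusted p = 0.0578), with 676 ± 71.3, 988 ± 214 and 1018 ± 227 CPM in wild type, clone 1 and clone 2. Its adjusted p ran from 6.31e-05 to 0.193 over the alternatives, and it was called with DESeq2's test (0.0247), the replicate block, the sample-number term (0.0413) and without clone 1 replicate 1 (0.0135). HERVK13-int fell by 0.99 (SE 0.13, adjusted p = 0.000195). It belongs to the list of other HERV-K, where 0 rose and 3 fell (0 and 1 adjusted over the list alone, 2 and 3 at an unadjusted p below 0.05, 0 and 3 with DESeq2; list adjusted p = 0.827). Reads from repeats align to many copies, so subfamilies can share reads, and the copies of origin were not analysed here.

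**Figure D4:**
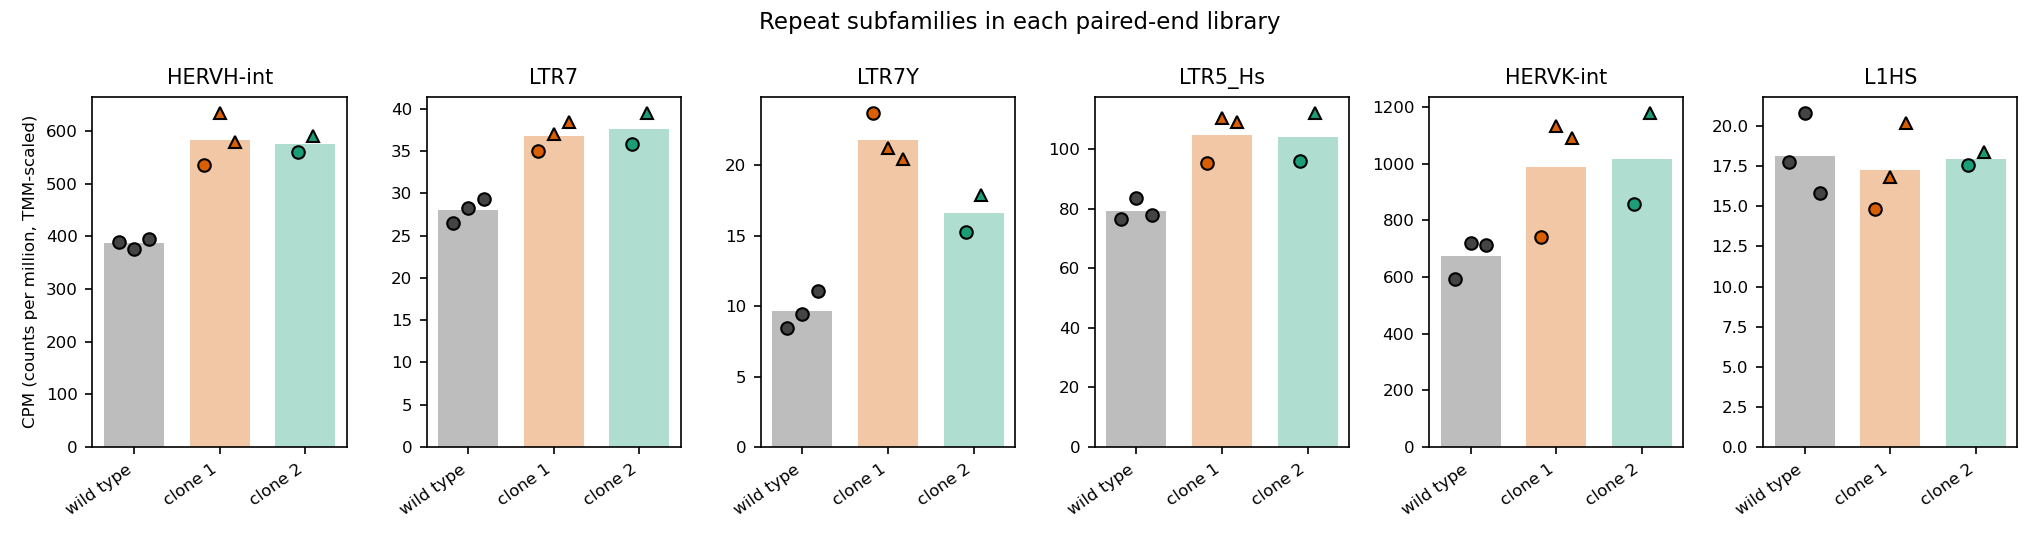
CPM of HERVH-int, LTR7, LTR7Y, LTR5_Hs, HERVK-int and L1HS in each paired-end library, with bars at the group means, circles for sample numbers 1 to 5 and triangles for 11 to 13. The means of HERVH-int are 386 CPM in wild type and 583 and 575 CPM in the clones, and those of L1HS are 18.1, 17.3 and 18 CPM.

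Few other repeats were called, and the balance of rises and falls depended on the block of sample numbers. In the mean of the clones 19 repeats rose and 8 fell, against 11 and 29 with the sample-number term and 10 and 51 in the first block alone. In clone 1, 11 rose and 13 fell, against 4 and 68 with the term. In both clones 8 subfamilies rose and 1 fell, against 4 and 6 with the term, with 5 shared. Besides those named, MER41G (0.75), MER61E (0.47) and Ricksha_c (0.35) rose without it. Adjusted over the repeats alone 4 rose and 1 fell, and 5 were called in all without any 1 wild type replicate or without clone 1 replicate 2 or 3, against 14 without clone 1 replicate 1. With the sample-number term the clone 1 calls of LTR7B (adjusted p = 0.102), MER41G (0.282), MER61E (0.174) and Ricksha_c (0.262) ended. In the mean of the clones, MER41G lost its call with the sample-number term, in the first block alone and without wild type replicate 1 (up to 0.0963). Ricksha_c lost it under the same block fits and without wild type replicate 1 or 3 or clone 2 replicate 2 (up to 0.1). Of 286 ERV1 subfamilies 15 rose, led by MER83B (1.53; 0.49 in clone 1 and 2.56 in clone 2) and LTR7Y, and 3 fell, MER95 (-0.49), HERVIP10F-int (-0.48) and LTR10G (-0.45) (8 and 1 adjusted over the list alone; list adjusted p = 0.510). With the sample-number term 8 rose and 11 fell, and in the first block alone 8 and 14. MER83B lost its call with the knockout libraries as 1 group (0.195), MER95 without wild type replicate 1 or 3 or clone 2 replicate 1 (up to 0.114). HERVIP10F-int lost it with the replicate block and without wild type replicate 1 or 2, clone 1 replicate 2 or either clone 2 replicate (up to 0.127). Of 39 ERVK subfamilies 1 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.510). Of 118 ERVL subfamilies LTR16B1 (0.35) rose and LTR89 (-0.38) fell (0 and 0 adjusted over the list alone; list adjusted p = 0.901). The ERVL list was called lower with the sample-number term (0.00977, 1 rose and 3 fell). LTR16B1 lost its call with the knockout libraries as 1 group and without any 1 wild type replicate, clone 1 replicate 3 or clone 2 replicate 1 (up to 0.139). LTR89 lost it with that grouping, with the replicate block, with DESeq2's test and without any 1 library except clone 1 replicate 3 (up to 0.166). Of 41 internal HERV regions 4 rose, among them HERVIP10B3-int (0.38), and 2 fell, HERVK13-int and HERVIP10F-int, the same adjusted over the list alone (list adjusted p = 0.199). HERVIP10B3-int lost its call with the sample-number term, in the first block alone and without any 1 wild type or clone 2 replicate or clone 1 replicate 2 (up to 0.181).

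The lists of other L1 and of DNA transposons were called lower in clone 1 with the preset correlation, with hardly a member called in the mean of the clones. For 120 other L1 subfamilies, 1 rose (L1PBa1, 0.29) and 1 fell (L1M3a, -0.36), and 0 adjusted over the list alone (median -0.15, adjusted p = 0.00314, or 0.997 with an estimated correlation and 0.817 with fry). The median was -0.285 in clone 1 (adjusted p = 1.51e-08, or 0.929 with an estimated correlation and 0.583 with fry) and 0.00248 in clone 2 (0.995). The list was called lower in clone 2 too with the sample-number term (0.00364), and in the mean of the clones the median was -0.322 (4.72e-10). The uncorrected test of the mean of the clones did not call the list without wild type replicate 1 (0.218), wild type replicate 2 (0.247) or clone 1 replicate 1 (0.0821). For 223 DNA transposons, 1 rose (Ricksha_c) and 1 fell (MER97d, -1.02), and 0 adjusted over the list alone (median -0.12, adjusted p = 0.0185, or 0.997 with an estimated correlation, 0.907 with fry and 0.0631 with GC correction). The GC correction left repeats as they were, so the last value changed only with the genes that camera compared them with. The median of the DNA transposons was -0.278 in clone 1 (adjusted p = 3.15e-08, or 0.929 with an estimated correlation and 0.612 with fry) and 0.0350 in clone 2 (0.388). The median in the mean of the clones was -0.300 with the sample-number term (3.25e-07), and the list was not called in clone 2 (0.122). The clones differed in both lists with the preset correlation (2.21e-16 and 3.24e-21) but not with an estimated one (0.768 each). In the mean of the clones the list of DNA transposons was not called without wild type replicate 1 (0.673) or 2 (0.657), clone 1 replicate 1 (0.303) or 2 (0.1), or clone 2 replicate 1 (0.156). Leaving out wild type replicate 1 ended the calls of L1PBa1 (0.102), L1M3a and MER97d (0.1). So did leaving out wild type replicate 3 for both L1 members, wild type replicate 2 and clone 2 replicate 1 for L1M3a, and clone 2 replicate 2 for L1PBa1 (adjusted p up to 0.0874 for L1M3a and 0.124 for L1PBa1). L1PBa1 also lost its call with the sample-number term (0.141) and in the first block alone. The median log2 fold change of all repeats was -0.18 in clone 1, 0.06 in clone 2 and -0.06 in their mean.

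In the mean of the clones, 0 of 8 young L1, 0 of 51 Alu and 0 of 6 SVA subfamilies were called. This held for edgeR and DESeq2, over all features and adjusted over the list alone. The list adjusted p from camera was 0.807, 0.990 and 0.231. In clone 2, 1 SVA subfamily rose, also adjusted over the list alone. The lists of young L1, Alu and SVA had 0, 1 and 2 members at an unadjusted p below 0.05. With the sample-number term 2 of the young L1 subfamilies fell and that list was called lower (median -0.278, adjusted p = 0.00401 with the preset correlation, the only one used with the term). Without the term the adjusted p of young L1 was 0.997 with an estimated correlation. L1HS, the L1 subfamily still mobile in humans, stood at -0.04 (adjusted p = 0.854), with a sign that turned without wild type replicate 2 (0.06). The smallest p of these lists belonged to L1PA7 (-0.14, adjusted p = 0.595), AluYg6 (-0.22, 0.111) and SVA_F (0.26, 0.0724). SVA_F was called with no filter on low counts (0.00792) and without clone 1 replicate 1 (0.0364) or 2. The lists of HERV9 and LTR12 (10 members, list adjusted p = 0.510), HERV-L and MLT2 (21, 0.995), THE1 and MST (23, 0.979), ERVL-MaLR (77, 0.934) and satellites (15, 0.995) also had 0 called members with edgeR or DESeq2 or adjusted over the list alone. They had 2, 0, 1, 1 and 1 members at an unadjusted p below 0.05. The ERVL-MaLR list was called lower with the sample-number term (0.0237). Their members with the smallest p included HERV9-int (0.46, adjusted p = 0.0941), MLT2B3 (0.12, 0.179), THE1-int (0.27, 0.110) and CER (-0.65, 0.137). HERV9-int was called with no filter on low counts (0.0247), with the replicate block (0.0273) and without clone 1 replicate 1 (0.0332). Of 6 HERV-E and LTR2 subfamilies HERVE-int rose (0.22, adjusted p = 0.0240) and 0 fell, also adjusted over the list alone (list adjusted p = 0.424). It lost its call with the sample-number term, in the first block alone and without any 1 wild type replicate or clone 2 replicate 2 (up to 0.163). HERV17-int of the HERV-W family stood at 0.13 (adjusted p = 0.700), with a negative sign under the sample-number term (-0.18), in the first block alone (-0.19) and without wild type replicate 3 (-0.02).

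The 2 RBM4 knockout clones differed from each other in single genes. Whether they carry the same edit of RBM4 is not given in the sources used here. LXN, a carboxypeptidase inhibitor gene, stood at 6.84 CPM in wild type and 6.38 CPM in clone 2 but 0.0486 CPM in clone 1 (clone 2 against clone 1, log2 fold change 7.01, SE 0.23, adjusted p = 4.20e-10). LXN had 6 counts in clone 1, so its SE is likely too small. The microRNA host gene MIR924HG behaved alike (6.20, SE 0.37). PDGFRA reached 39.2 ± 1.73 CPM (SD, n = 2) in clone 2 and 1.59 ± 0.0971 CPM (n = 3) in clone 1 (4.61, SE 0.11). The tumour suppressor gene DLC1 (4.26), the secreted factor gene ANGPTL2 (3.94) and the gap junction gene GJA1 (3.57) were also higher in clone 2. SERPINB1, a protease inhibitor gene, had 1 count in clone 2 against 15.2 CPM in clone 1, a ratio of 1328 (95% interval 238 to 52472). Lower in clone 2 were also SLC17A9 (-8.13), a vesicular nucleotide transporter gene at 32.8 CPM in clone 1 and 0.115 CPM in clone 2, the amino acid transporter gene SLC7A3 (-4.78), MYOM1 (-3.64), STXBP2 (-3.48) and ZNF385D (-3.44). In all, 434 features differed, 224 genes and 4 repeats higher in clone 2 and 206 genes and 0 repeats lower (1980 features at an unadjusted p below 0.05). The count was 284 and 224 without clone 2 replicate 1 and 2, which leaves 1 library in that clone, assumed to vary like the others. Of lists not called in the mean of the clones, 6 were called in clone 2 with the preset correlation. They were NF-kB targets (adjusted p = 0.0223), mesenchymal and matrix genes (0.0276), ERV1 (0.00789), ERVL-MaLR (0.0417) and internal HERV regions (0.0223), which were higher, and cytosolic ribosomal proteins (0.00790), which were lower. None of the 6 was called in clone 2 with an estimated correlation (0.225 to 0.999), and with the sample-number term only NF-kB targets were among them (0.0419, the others 0.0732 to 0.985). In clone 1 their adjusted p lay between 0.106 and 0.742.

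In the single-end pair, RBM4 stood at 84.7 CPM in the wild type library and 25.3 CPM in the knockout library, a log2 fold change of -1.74. Of 1517 genes called the same way in both clones and measured there, 1442 (95.1%, 95% interval 93.8 to 96.1) had the same sign, as did 335 of 339 changed at least 2-fold (98.8%, 97.0 to 99.7). ALDH1A2 was at -6.44 and VCAM1 at 3.83. Of the gene lists called in the mean of the clones, 2 had a median of the other sign in the pair. They were the unfolded protein and integrated stress response (-0.07) and cholesterol synthesis (-0.0023). The other called gene lists kept their sign, from -0.20 (DNA replication genes) to 0.36 (imprinted genes). Genes in general stood slightly lower in the knockout library of the pair, with medians of -0.015 to -0.047 by GC content. Lists not called in the mean of the clones fell about as far, such as heat shock genes (-0.21) and cytosolic ribosomal proteins (-0.19). Falls of list medians in the pair therefore say little of the clones. Repeats in general stood higher in the knockout library of the pair, with list medians from 0.0919 (Alu) over 0.274 (ERV1), 0.275 (DNA transposons) and 0.282 (other L1) to 0.434 (HERV-K HML-2 and LTR5). Signs of repeats in the pair therefore say little of the clones. HERVH-int was at 0.61 and LTR7Y at 0.70, and HERVK13-int was at -0.28 against -0.99 in the clones. LGALS8 (-0.50) and SLC4A5 (0.39) had much smaller changes there than in the clones. Across genes and repeats, which are not independent replicates, the fold changes of the pair correlated at 0.465 (Spearman 0.282) with clone 1 and 0.678 (Spearman 0.460) with clone 2. These values compare 2 libraries and have no replicate check.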

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

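The tests of GC content, sample-number block, repeat shift and chromosome segments below were chosen only after the results were seen; the test of clone 2 against clone 1 was planned.

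The clones differed in 37 of the named features by edgeR's test of clone 2 against clone 1, although both carry the knockout. Log2 differences, clone 2 minus clone 1, of genes that rose most in the mean of the clones were 1.42 for VCAM1, 4.61 for PDGFRA, 2.12 for SGCD, -0.83 for FOXF1, 2.93 for BMP7 and 0.68 for PRDM16. Among those that fell most they were 2.5 for ALDH1A2, -3.44 for ZNF385D, -2.94 for ITPRIPL1, -0.92 for MYO5C, 2.64 for CSRP1, -2.44 for SLITRK3, -3.06 for ABCB1, -1.39 for CSMD1 and -2.31 for PCDH17. In immune and silencing genes the differences were -2.18 for CGAS, 0.91 for APOBEC3C and -1.55 for APOBEC3B. In other list members they were -0.45 for RORA, 1.34 for HRK, -1.61 for THBS2, -0.47 for KIT, 1.59 for ESRG, 0.37 for LIN28B, 1.38 for L3MBTL1, -2.36 for ZNF804A and 2.07 for the repeat MER83B. The genes that differed most were LXN (7.01), MIR924HG (6.20), DLC1 (4.26), ANGPTL2 (3.94), GJA1 (3.57), SERPINB1 (-10.04), SLC17A9 (-8.13), SLC7A3 (-4.78), MYOM1 (-3.64) and STXBP2 (-3.48). Fitted values of SERPINB1 rest on 1 count in clone 2.

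Lists differed between the clones in 20 cases with the preset correlation, and in none with an estimated correlation (adjusted p from 0.626 to 0.771). Median log2 differences, clone 2 minus clone 1, were -0.0217 for splicing regulators, 0.0448 for the unfolded protein and integrated stress response, 0.11 for cholesterol synthesis and -0.0732 for cytosolic ribosomal proteins. They were 0.0755 for mesenchymal and matrix genes, -0.0170 for neuronal genes, 0.0637 for pluripotency genes and 0.11 for imprinted genes. For repeats they were 0.16 for other HERV-K, 0.23 for HERV9 and LTR12, 0.22 for HERV-L and MLT2, 0.21 for THE1 and MST, and 0.19 for ERV1. They were 0.12 for ERVK, 0.20 for ERVL, 0.21 for ERVL-MaLR, 0.14 for internal HERV regions, 0.28 for other L1, 0.31 for DNA transposons and 0.19 for satellites.

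The first pattern is the 1549 genes changed the same way in both clones, which might follow the GC trend or the sample-number block rather than the knockout. With GC correction, genes changed at least 2-fold kept a median share of 0.964 of their log2 fold change (quartiles 0.915 to 1.01, 344 of 370 still called in both clones). Genes changed less kept 0.764 (quartiles 0.620 to 0.907, 661 of 1179 still called). The trend is thus argued against as the whole cause, but it may have added to the smaller changes. The 518 smaller changes no longer called in both clones had a median size of 0.305 before and 0.179 after correction (quartiles 0.257 to 0.387 and 0.134 to 0.265). All 518 came nearer to 0, while their median SE went from 0.0592 to 0.0515, so those calls ended by the smaller change. Their share left was 0.607 (quartiles 0.491 to 0.709), against 0.866 (0.772 to 1.02) in the 661 still called. Within sample numbers 1 to 5 alone, with 1 library per clone, the shares were 0.984 and 1.02, which argues against the block for these genes. Each clone has libraries in both blocks, so genes that differ by block vary within a clone. Such genes were less likely to be called, so the choice of genes favoured shares near these values. What stays open is whether RBM4 loss or a state carried by the founder cell of each clone set these genes, since no rescued cells were analysed here and the wild type libraries are shared.

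The second pattern is the rise of HERVH-int, LTR7, LTR7Y and LTR5_Hs, which could come from a general shift of reads from repeats or from the block. The other repeat subfamilies had a median log2 fold change of -0.0574 (quartiles -0.153 and 0.0463), below all 4 rises, which argues against a general shift in the paired-end libraries. In the single-end pair, which has no replicates, repeat lists in general were higher (median 0.274 for ERV1 and 0.282 for other L1), so a general shift stays open there. Within sample numbers 1 to 5 the 4 kept a median share of 0.832 of the change (HERVH-int 0.856, LTR7 0.809, LTR7Y 0.997, LTR5_Hs 0.665), which argues against the block as the whole cause. HERVK-int kept 0.412 there, as a block difference would give, and its block term was 0.53 (adjusted p = 0.00229 by edgeR's test). With the sample-number term, however, HERVK-int was called higher in the clones, as given above. A block difference may therefore be only part of its rise. The block term of LTR5_Hs also passed its test (0.21, adjusted p = 0.0445), so a block difference may have added to its rise. A biological explanation by RBM4 loss stays open, as do clone founder states, which were not tested.

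The third pattern is the 434 features that differ between the clones, which might come from copy number of a chromosome segment, the GC trend or the block. Over 280 bins of 10 Mb the largest absolute median difference was 0.114, which argues against a gained or lost large segment. GC correction kept 433 of the calls and the sample-number term kept 434. Each clone has libraries in both blocks. The GC correlations of the libraries cover a like range in clone 1 (-0.08 to 0.54) and clone 2 (-0.10 to 0.52). Neither fit could therefore move the difference between the clones much, and the kept calls cannot decide about either cause. Differences of the founder cells and smaller genomic changes stay open, as none was tested.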

How the results depend on the processing

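The GC correction, the sample-number term, the first block of sample numbers alone and the left-out and divided libraries for the correlation were chosen after seeing the data; the other alternatives were planned. RBM4 stayed called in both clones under every alternative, from -1.73 to -1.70 with each library left out. No called feature changed sign in a fit with a library left out. Leaving out 1 library gave ranges of 1605 to 3229 features for clone 1 (3321 with all), 1033 to 2747 for clone 2 (2236), and 1847 to 4251 for the mean of the clones (3725). They were 224 to 418 for clone 2 against clone 1 (434), 766 to 1737 genes in both clones (1549), 5 to 14 repeats in both clones (9) and 12 to 18 lists (14). Fewer samples can lower these counts by construction, and where they rose the cause was not tested. A 1.5-fold minimum left 1027 features in clone 1, 1005 in clone 2, 1084 in the mean, 552 genes and 3 repeats in both clones, by its construction. Repeats adjusted over the repeats alone gave 5 in both clones, where the adjustment no longer draws on genes. Clone 2 against clone 1 gave 688 features with no filter on low counts and 224 within the first block of sample numbers, which has 1 library per clone; the cause of the former was not tested.

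No list was called with an estimated correlation (0 of 46 against 14), and 22 were in the first block of sample numbers; the cause was not tested. The correlation of the clones' fold changes was 0.5002 over repeats alone (0.649 over all features) and 0.584 to 0.679 with 1 library left out; the cause was not tested. It was 0.476 with the wild type libraries divided between the clones, where no library is shared and each fold change rests on fewer. Of the genes changed in both clones, 58.6% rose, 45.9% with the sample-number term and 42.0% in the first block alone. With GC correction 731 rose and 648 fell, 1014 of 1558 features being shared with the uncorrected fit.

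Reversed signs were rare. The RBM14 mean of clones, not called, was at -0.000487 with TMM factors from genes only, -0.13 with GC correction, -0.0170 without wild type replicate 3, -0.00341 without clone 1 replicate 3 and -0.0347 without clone 2 replicate 1 (range with 1 library left out -0.0347 to 0.0424). HERV17-int was at -0.18 with the sample-number term, -0.19 in the first block alone and -0.0207 without wild type replicate 3 (up to 0.204 with 1 library left out), and L1HS at 0.0605 without wild type replicate 2. SLC7A3 was at 1.12 (adjusted p = 0.587) with all knockout libraries as 1 group, since the clones went opposite ways. For the others the cause was not tested. Of 140 named results 127 were called, 60 of them under every alternative.

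Of 7 pairs of libraries with the same replicate number, 2 correlated above 0.1, and the 7 ran from -0.233 to 0.253. The 2 were the pairs between the clones (0.253 for replicate 1 and 0.197 for replicate 2), which also share a block of sample numbers. Replicate numbers thus did not pair wild type with the clones. Between the clones, number and block cannot be told apart. With the replicate block the counts were 3716 for clone 1, 2526 for clone 2, 4248 for the mean, 431 between the clones, 1814 genes and 11 repeats in both clones and 15 lists. Depth limits genes at low levels most: SERPINB1 had 1 count in clone 2 and SPRY4 had 2 in wild type, so that their ratios have wide intervals.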

Other observations

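The GC-corrected and sample-number fits and the comparison of the single-end pair with each clone over the genes that differ between the clones were chosen after the results were seen; the other tests in this part were planned.

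Some genes moved in opposite directions in the 2 clones. Of features called in both clones, 37 went opposite ways against wild type. SERPINB1 rose by 0.57 in clone 1 (10.2 to 15.2 CPM) and fell in clone 2, as did SLC17A9 (0.68 in clone 1 and -7.44 in clone 2) and the amino acid transporter gene SLC7A3 (1.82 and -2.96). DLC1, a tumour suppressor gene, fell by 0.87 in clone 1 and rose by 3.40 in clone 2. STXBP2, a vesicle fusion gene, rose in clone 1 alone (3.23, from 0.648 to 6.10 CPM; -0.25 and adjusted p = 0.73 in clone 2). Cholesterol synthesis was called in clone 2 (6 genes rose and 0 fell, camera adjusted p = 0.000176, or 0.349 with an estimated correlation) and not in clone 1 (3 rose and 2 fell, 0.553). The list differed between the clones with the preset correlation (6.88e-06) but not with an estimated one (adjusted p = 0.626).

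The single-end knockout library resembled clone 2 in the genes that set the clones apart. Of 412 such genes measured in the single-end pair, 337 (81.8%, 95% interval 77.7 to 85.4) had a fold change nearer to that of clone 2. Its LXN was at -0.05, MIR924HG at 0.23, PDGFRA at 4.69, GJA1 at 4.44, SLC17A9 at -7.03 and SLC7A3 at -3.07. The labels do not say which clone the library came from.

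A smaller set of genes was called the same way in both clones under the uncorrected fit, the GC-corrected fit and the fit with a sample-number term: 889 genes, of which 552 rose, 337 fell and 311 changed at least 2-fold.

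Other splits of the libraries were compared with the real one. For the mean of the clones, 1 of 100 splits of the 8 libraries, the real one, gave at least 3725 called features. The highest other, 3687, kept the 3 wild type libraries together and exchanged only libraries between the clones. Splits that mixed wild type and knockout libraries gave up to 971, but such mixing widens the spread within groups and lowers the count by construction. The splits therefore cannot exclude chance, and they do not address chance differences between founder cells. For clone 1, the 6 libraries allow 10 splits, too few for a share under 0.05; the real split gave 3321 and the highest other 269. For the list tests, 60 of 100 splits gave at least 14 called lists and the highest gave 31, so chance cannot be excluded for the number of called lists.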
